A study of Homo sapiens with 2 samples.

How the data were processed

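Kidney organoids of the established human line SCTi004-A were profiled by 3′ single-cell RNA sequencing on the PIPseq V platform, which captures cells in particle-templated emulsions, with 1 library of the 2D and 1 of the 3D format. The authors deposited a matrix of raw counts per gene and barcode for each library, whole numbers with no normalization per the file headers. Reads were mapped to hg38, per the submitters' processing notes, while the aligner, the counting tool, the gene annotation, the treatment of molecular identifiers and the calling of cells were not given in the sources used here. The matrices hold 40429 genes, given with symbols and Ensembl identifiers, and 57 symbols that occur more than once were kept apart. The authors also deposited 1 table of other values, a text label of cell type per barcode from a manual classification, per the file headers. It labels 19625 barcodes under 4 library suffixes. All barcodes of 1 suffix occurred in the 2D library and of another in the 3D library, with no overlap, which gave 8963 labelled cells. The 10662 cells under the other 2 suffixes matched neither library and were not used here. In both libraries the labelled barcodes were exactly those with more than 2000 and fewer than 10000 genes and less than 10% mitochondrial counts. The unlabelled barcodes, 4880 in 2D and 1990 in 3D, entered only the closing section.

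The groups, the comparisons, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Shares of the 11 deposited cell types were given over all annotated cells and over nephron cells, with exact (Clopper-Pearson) 95% binomial intervals, and ratios of shares with exact conditional intervals. Counts were summed per library and cell type for the 5 types with at least 100 cells in each library, turned into counts per 1000000 (CPM), and compared as the ratio of 3D to 2D with exact conditional Poisson 95% intervals. With 1 library per group no test, p-value or standard error was computed, since cells are not replicates. A gene was counted as at least 2-fold apart if its ratio reached 2 in either direction with at least 50 CPM and 20 counts in the higher library. Doublets were not removed and no doublet caller was run, nor was RNA from other cells subtracted. Shares of cells with G2/M counts were taken after each cell was thinned at random to 2000 counts, with at least 2 counts over the list required.

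Named genes were chosen by size. For each type they were the 5 highest and 5 lowest by log2 ratio with 5 CPM added, among genes with at least 50 CPM and 20 counts in the higher library and at least 25% there of the CPM of the highest type, a guard against RNA from other cells. Across types they were the 10 genes with the greatest and the 10 with the lowest value of their weakest ratio over the 5 types, with the same sign and at least 50 CPM in each. From each described list, up to 4 members with the highest mean CPM or the largest ratio were taken. Mitochondrial and ribosomal protein genes, genes known only by a clone or identifier, and genes of the sex chromosomes that report sex were left out, and 1 lower gene of Early Nephron cells that met the rule is not shown. Of 45 lists of cell type markers and pathway genes, those with at least 5 measured members (10 CPM in either library) were summarised by the median of log2 ratios with 1 CPM added. Each median was placed among 10000 random lists of equal size matched on mean expression in 20 bins, as a description of these libraries. Gene coordinates, GC content and genomic span came from GENCODE release 29 on hg38, in which 36059 of the 40429 genes were found.

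The depth was 49732892 counts in 2D and 60206570 in 3D. Counts summed per compared type ran from 1439487 (Early Nephron, 2D) to 13165063 (stroma, 3D), so that intervals are widest in Early Nephron cells. On simulated counts with known answers, in which 200 genes per type were changed, genes changed 3-fold were recovered as at least 2-fold apart in 97.0% of cases in distal cells, 98.5% in podocytes, 98.5% in proximal cells, 94.0% in Early Nephron cells and 100% in stroma. For 4-fold changes these were 100%, 100%, 98.5%, 97.0% and 100%. None of the genes changed 1.5-fold reached 2-fold, and of the unchanged genes 1 of 3540 did in Early Nephron cells and 0 in the others. Intervals held the true ratio of unchanged genes in 95.0% to 95.4% of cases. The simulated counts followed the Poisson model that the intervals assume, without variation between cells. Recovery and coverage therefore check the computation and do not show how far real counts vary. In stroma, 7.00% of 100 simulated unchanged lists fell outside the central 95% of random lists, and 100% of lists shifted by 0.5 lay above it. Alternatives covered the scaling (median of ratios, or totals without mitochondrial and ribosomal protein genes), the mean over cells in place of the sum, the CPM minimum (20 or 200), the guard against RNA from other cells, the cells used, the denominator of shares, the pseudocount and membership of lists, and the depth and minimum of the G2/M shares. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and the random seed was 7.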

Results

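Single-cell transcriptomes were measured in kidney organoids grown for 18 days from the human induced pluripotent stem cell line SCTi004-A, an established line, at passage 35. Organoids were made with a commercial differentiation kit, either as a 2D monolayer or as 3D aggregates, and both formats received the cloning supplement CloneR2 at seeding. One question was posed by the design: how the cell types and their transcripts compare between the 2D and the 3D format. There was 1 library per format, so no difference has a replicate check, no test was made, and each comparison is between these libraries rather than between formats in general. The 2D library held 49732892 counts over 10036 barcodes and the 3D library 60206570 counts over 5797 barcodes. The deposited cell type labels covered 5156 barcodes of the 2D library (51.4%) and 3807 of the 3D library (65.7%). Annotated cells had a median of 6213 counts and 2799 genes in 2D and of 9260 counts and 3748 genes in 3D, with a median mitochondrial share of 4.73% and 4.58%. Brackets after a share or a ratio hold its exact 95% interval, and these intervals cover counting error only. Before dissociation, the mesenchymal layer of the 2D wells was crudely removed with trypsin and forceful pipetting, and the 2D cells were then exposed to trypsin for longer than the 3D cells.

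Cells that the authors named Early Epithelial made up 53.7% (52.4-55.1) of annotated cells in 2D and 0.236% (0.108-0.448) in 3D, a share 227-fold (120-498) higher in 2D. These were 2771 and 9 cells. Cells of all nephron types together, from progenitors and podocytes to connecting tubule, made up 23.0% (21.9-24.2) of the 2D and 50.1% (48.5-51.7) of the 3D library, a ratio of 2.18 (2.03-2.34). Distal cells took 6.13% (5.49-6.82) in 2D and 15.2% (14.1-16.4) in 3D, a ratio of 2.48 (2.16-2.86). Proximal cells took 2.97% and 6.25%, a ratio of 2.11 (1.71-2.60), and podocytes with parietal epithelial cells took 10.6% and 17.1%, a ratio of 1.61 (1.43-1.81). The latter type is called podocytes below. Early Nephron cells took 2.87% and 7.22%, a ratio of 2.52 (2.05-3.09). Stroma made up 21.2% (20.1-22.4) in 2D, where the mesenchymal layer had been removed, and 38.8% (37.3-40.4) in 3D, a ratio of 1.83 (1.69-1.98). Endothelial cells were 1.38% and 0.946%, and the interval of their ratio of 0.687 (0.447-1.04) included 1. With Early Epithelial cells left out of the denominator, an alternative chosen after the data were seen, all nephron cells were 49.7% and 50.2%, a ratio of 1.01 (0.939-1.09). The ratio was then 1.15 (1.00-1.32) for distal, 1.17 (0.952-1.43) for Early Nephron, 0.977 for proximal cells, 0.746 for podocytes and 0.848 for stroma, so that the higher shares of these types in 3D rest largely or wholly on that 1 population. For endothelial cells it was 0.318 (0.207-0.482), while over all cells but without the 5% with the most counts it was 1.04.

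**Figure D1:**
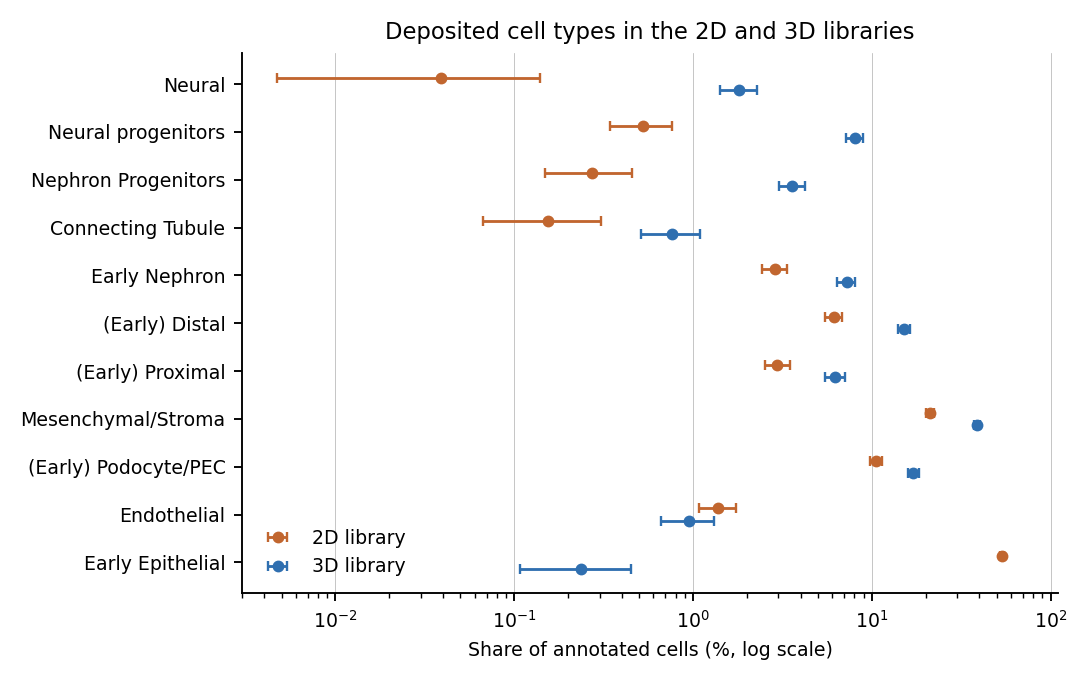
Share of annotated cells (%, log axis) that carried each deposited cell type name in the 2D and the 3D library, with exact 95% binomial intervals as bars. Early Epithelial cells stand at 53.7% in 2D and 0.236% in 3D, and neural progenitors at 0.524% and 8.04%.

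Within the nephron cells alone, the makeup was closer between the libraries. Podocytes were 46.1% (43.3-49.0) of the 1186 nephron cells in 2D and 34.1% (31.9-36.2) of the 1908 in 3D, a ratio of 0.739 (0.658-0.829). Distal cells were 26.6% and 30.3%, with a ratio of 1.14 (0.991-1.31), and proximal cells 12.9% and 12.5%, with a ratio of 0.967 (0.786-1.19). Early Nephron cells were 12.5% and 14.4%. Nephron Progenitors were 1.18% (14 cells) in 2D and 7.18% (137 cells) in 3D, a ratio of 6.08 (3.50-11.4). There were 0.872 tubule cells per podocyte in 2D and 1.30 in 3D, a ratio of 1.49 (1.27-1.76) that came to 1.08 among cells with at least 5000 counts, a minimum chosen after the data were seen. There were 2.07 distal cells per proximal cell in 2D and 2.43 in 3D, a ratio of 1.18 (0.914-1.52). Nephron cells per stromal cell were 1.08 and 1.29, a ratio of 1.19 (1.07-1.33). The removal of the mesenchymal layer from the 2D wells bears directly on this ratio, and how much stroma it took was not measured.

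Neural cells, an unwanted product of kidney differentiation, were more frequent in the 3D library. Neural progenitors made up 0.524% (27 cells) in 2D and 8.04% (306 cells) in 3D, a ratio of 15.3 (10.3-23.7) that came to 7.12 with Early Epithelial cells left out of the denominator. Cells named Neural were 2 and 69, or 0.0388% and 1.81%. Neural and neural progenitor cells per nephron cell came to 0.0245 in 2D and 0.197 in 3D, a ratio of 8.04 (5.46-12.2). The marker list for neural cells summed to 299 counts per 1000000 (CPM) over all annotated 2D cells and 663 CPM over all annotated 3D cells. In 2D, this list was also higher in Early Epithelial than in other annotated cells (median log2 ratio 0.998, 4 of 6 measured members higher). Other lists for cells outside the kidney lineage went the other way: the muscle list summed to 385 CPM in 2D and 125 CPM in 3D, and the cartilage list to 278 CPM and 115 CPM. No muscle or cartilage type was labelled, and such sums are levels of RNA, not numbers of cells. The pluripotency list summed to 66.0 CPM and 89.9 CPM, the melanocyte list to 58.7 CPM and 62.8 CPM, and the immune list to 149.9 CPM and 162 CPM.

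Expression was compared within the 5 types that had at least 100 cells in each library. The stromal cells of the 2D library were those left after the crude removal of the mesenchymal layer. Selection by that step was not separated from the format in any stromal comparison. In stroma, 3 genes of contractile smooth muscle were among those that were lower in the 3D library by the most. ACTA2, smooth muscle actin, was at 382 CPM in 2D and 28.3 CPM in 3D, which is 13.5-fold (12.2-15.1) lower. TAGLN was 10.4-fold (9.58-11.4) lower and ACTG2 19.8-fold (15.1-26.4) lower. DLK1, an imprinted gene of immature mesenchyme (chromosome 14, 100725705 to 100738224 on hg38), was at 181 CPM in 2D and 8.43 CPM in 3D, 21.5-fold (17.7-26.3) lower. ANKRD1, a target of the mechanosensitive YAP and TAZ pathway, had 511 counts in 2D stroma and 1 count in 3D stroma, so its 806-fold ratio has an interval from 144 to 31904. The named genes that were higher in 3D stroma were TMEM132C at 4.41-fold (3.70-5.28), the protease gene CTSK at 4.19-fold (3.48-5.07), the transcription factor genes GATA2 at 3.90-fold (3.20-4.81) and TWIST1 at 3.30-fold (2.79-3.92), and TEX14 at 3.18-fold (2.68-3.80). Without the 5% of cells with the most counts, the ratios of 3D to 2D were 0.112 for ACTA2, 0.103 for ACTG2 and 0.00202 for ANKRD1, each over 1.5 times that in all cells. In all, 37 genes were at least 2-fold higher and 125 at least 2-fold lower in 3D among 3994 genes with enough counts.

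The list of cholesterol synthesis genes was lower in 3D stroma. All 17 measured members were lower in 3D and 15 of them at least 2-fold, with a median log2 ratio of -1.73, while the central 95% of random lists matched on expression ran from -0.08 to 0.21. FDPS, farnesyl diphosphate synthase, was at 438 CPM in 2D and 151 CPM in 3D. These genes were also higher in 2D Early Epithelial cells than in other 2D cells (median 0.64), and at least 3 of 10 genes that lead in those cells were found in 12.6% of 2D and 0.0676% of 3D stromal cells, so that the difference was not separated from RNA or cells of that type. Markers of podocytes (-0.40) and of general nephron epithelium (-0.59) were lower in 3D stroma as well, the latter not with all detected members (0.17). The list of NF-kB targets and chemokines had a median of -1.75 (random lists -0.26 to 0.29), with all 8 members lower. The chemokine CXCL12 was at 725 CPM in 2D and 179 CPM in 3D and CCL2 at 119 CPM in 2D and 10.6 CPM in 3D. Genes of collagens and the interstitial matrix had a median of -0.47 (random lists -0.09 to 0.19), with 14 of 16 lower: COL1A1 was at 2992 CPM in 2D and 1426 CPM in 3D, TNC at 232 CPM in 2D and 63.9 CPM in 3D and THBS1 at 56.8 CPM in 2D and 9.65 CPM in 3D, while COL3A1 was at 2225 CPM in 2D and 1906 CPM in 3D. The contractile list as a whole, targets of the transcription factor SRF, differed less, with a median of -0.51 (random lists -0.08 to 0.18) and 5 of 16 members at least 2-fold lower, and its most abundant member TPM1 was at 826 CPM in 2D and 561 CPM in 3D. S phase genes were higher in 3D stroma, 17 of 18, with a median of 0.61 (random lists -0.07 to 0.21). PCNA, the replication clamp, was at 147 CPM in 2D and 198 CPM in 3D and MCM2, a subunit of the replicative helicase, at 44.6 CPM in 2D and 94.0 CPM in 3D. Targets of WNT signalling were also higher, 7 of 8, with a median of 0.57 (random lists -0.25 to 0.31). LEF1 was at 24.3 CPM in 2D and 46.9 CPM in 3D, and LGR5 at 1.68 CPM in 2D and 15.7 CPM in 3D, a ratio of 9.37 (5.46-17.4).

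Podocytes kept NPHS1, the slit diaphragm gene, and PODXL, the podocalyxin gene, at similar levels in the libraries, while several other podocyte genes were lower in 3D. This deposited type also holds parietal epithelial cells, so changes within podocytes were not separated from a different mix of the cells. NPHS1 was at 2708 CPM in 2D and 2949 CPM in 3D and PODXL at 2240.2 CPM in 2D and 2039 CPM in 3D. NTNG1, a membrane-anchored netrin gene (chromosome 1, 107140007 to 107483458 on hg38), was at 127 CPM in 2D and 11.9 CPM in 3D, 10.7-fold (8.53-13.6) lower. MAGI2, a slit diaphragm scaffold, was at 1819 CPM in 2D and 778 CPM in 3D and TCF21, a transcription factor of podocytes and stroma that stands in both marker lists, at 915 CPM in 2D and 424 CPM in 3D. The podocyte list as a whole had a median log2 ratio of -0.42 (random lists -0.15 to 0.22), with 11 of 15 members lower and 4 of them at least 2-fold. NPW, a neuropeptide gene, was 9.00-fold (7.49-10.9) lower, SAMD11 7.62-fold (5.67-10.4), ST6GALNAC3, a sialyltransferase gene, 5.23-fold (4.83-5.67), and the chemokine CXCL14 5.21-fold (4.67-5.81). Higher in 3D were DAPL1 at 3.80-fold (3.09-4.71), RAC3, a small GTPase gene, at 2.75-fold (2.25-3.37), HSPH1, a heat shock protein gene, at 2.70-fold (2.15-3.41), MAF1, a repressor of RNA polymerase III, at 2.68-fold (2.30-3.14), and DDIT4 at 2.46-fold (2.20-2.75). Genes at least 2-fold apart were 23 higher and 85 lower in 3D among 4149.

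General markers of nephron epithelium were higher in 3D podocytes, 12 of 13, with a median of 0.40 (random lists -0.18 to 0.23). Here too the mix with parietal epithelial cells was not separated. The keratin genes KRT18 and KRT8 were at 287 CPM in 2D and 446 CPM in 3D and at 204 CPM in 2D and 383 CPM in 3D. Notch targets had a median of 0.35 (random lists -0.23 to 0.26), with HES4 at 349 CPM in 2D and 445 CPM in 3D and HEY1 at 71.2 CPM in 2D and 119 CPM in 3D, while HES1 was lower at 238 CPM in 2D and 147 CPM in 3D. The NF-kB list had a median of -1.49 with all 6 measured members at least 2-fold lower, among them NFKBIA at 134 CPM in 2D and 48.2 CPM in 3D and the chemokine CXCL1 at a ratio of 0.0368 (0.0144-0.0791). Stromal markers were lower in 3D podocytes, with a median of -0.63 (random lists -0.21 to 0.24). DCN was at 127 CPM in 2D and 19.2 CPM in 3D and LUM, which was also among the leading genes of 2D Early Epithelial cells, at 22.2 CPM in 2D and 1.84 CPM in 3D. RNA from other cells was not removed from these values.

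In proximal cells, most genes of the mature proximal tubule were higher in the 3D library. SLC22A6, the organic anion transporter OAT1 (chromosome 11, 62936385 to 62984983 on hg38), was at 25.1 CPM in 2D and 152 CPM in 3D, 6.06-fold (4.70-7.94) higher. FABP1, a fatty acid binding protein gene, was at 142 CPM in 2D and 354 CPM in 3D. The most abundant members differed less, with AGT, angiotensinogen, at 1002 CPM in 2D and 1265 CPM in 3D and SLC3A1, an amino acid transporter, at 353 CPM in 2D and 291 CPM in 3D. The proximal list had a median log2 ratio of 0.50 (random lists -0.16 to 0.29), with 11 of 15 members higher. Further named genes higher in 3D were PTGDS, a prostaglandin synthase gene, at 4.92-fold (4.13-5.91), MFSD3 at 3.89-fold (2.81-5.51), and 2 genes of protein folding in the endoplasmic reticulum, SDF2L1 at 4.57-fold (3.30-6.50) and DNAJB11 at 3.63-fold (2.77-4.83). Lower in 3D were TCIM at 6.46-fold (4.64-9.14), ANKRD1 at 5.59-fold (4.31-7.31), the stress-induced transcription factor gene ATF3 at 5.17-fold (4.21-6.37), BIRC7 at 4.77-fold (4.01-5.68) and the proteoglycan gene BGN at 4.01-fold (3.05-5.30). Without the 5% of cells with the most counts, the ratios of 3D to 2D were 4.50 for SLC22A6, 3.68 for PTGDS and 0.329 for TCIM. They were 7.03 for SDF2L1 and 5.52 for DNAJB11. Each of these lay outside its interval in all cells. Notch targets were lower, all 10 measured members, with a median of -0.64 (random lists -0.34 to 0.29), and HES1 was at 641 CPM in 2D and 322 CPM in 3D. At least 2-fold apart were 57 genes higher and 52 lower among 3679. The larger side turned with the scaling, with 45 higher and 60 lower by the median of ratios.

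In distal cells, DEFB1, the beta-defensin gene of the distal nephron, was at 1192 CPM in 2D and 3132 CPM in 3D, 2.63-fold (2.55-2.71) higher. DDIT4, a stress-induced inhibitor of mTOR signalling (chromosome 10, 72273920 to 72276036 on hg38), was at 118 CPM in 2D and 449.7 CPM in 3D, 3.81-fold (3.45-4.21) higher. HSPH1 was 4.30-fold (3.19-5.90) higher, the noncoding RNA gene DLEU2 3.19-fold (2.59-3.95) and the stress transcription factor gene ATF5 3.13-fold (2.54-3.89). CCN1, a matricellular target of YAP and TAZ (chromosome 1, 85580761 to 85583962 on hg38), was at 839.6 CPM in 2D and 137 CPM in 3D, 6.12-fold (5.73-6.54) lower in 3D. The list of YAP and TAZ targets differed far less in distal cells, with a median of -0.16 (random lists -0.14 to 0.25) and 10 of 16 members lower. The other 4 named genes that were lower belong to the immediate response to stimuli: NR4A1 at 5.37-fold (4.34-6.66), ZFP36 at 3.22-fold (2.69-3.85), ATF3 at 3.14-fold (2.55-3.87) and KLF10 at 2.81-fold (2.37-3.33). Without the 5% of cells with the most counts, the ratios of 3D to 2D were 0.469 for ATF3, 0.372 for ZFP36, 0.237 for NR4A1 and 0.195 for CCN1. They were 3.44 for DDIT4 and 3.26 for DEFB1. Each of these lay outside its interval in all distal cells. The list of distal and connecting segment markers was within random lists (0.04, random lists -0.10 to 0.22): WFDC2 was at 2126 CPM in 2D and 1579 CPM in 3D and TMEM213 at 21.7 CPM in 2D and 47.1 CPM in 3D. Markers of the loop of Henle were lower, 5 of 7, with a median of -0.54 (random lists -0.27 to 0.36), with CLDN10 at 70.3 CPM in 2D and 44.5 CPM in 3D. SLC12A1, the target of loop diuretics, was low in both at 17.2 CPM in 2D and 8.30 CPM in 3D, and PPP1R1A went the other way at 16.9 CPM in 2D and 30.7 CPM in 3D. Genes at least 2-fold apart were 27 higher and 26 lower among 3994, and 20 and 41 by the median of ratios.

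Early Nephron cells of the 3D library carried more transcripts of podocyte genes, 10 of 12 measured members, with a median log2 ratio of 0.59 (random lists -0.21 to 0.24). NPHS1 was at 238 CPM in 2D and 404 CPM in 3D and PODXL at 19.5 CPM in 2D and 57.9 CPM in 3D. Stromal markers were lower, with a median of -1.20 (random lists -0.40 to 0.31): COL1A1 was at 110.5 CPM in 2D and 42.2 CPM in 3D and DCN at 24.3 CPM in 2D and 1.64 CPM in 3D. Named genes higher in 3D were MFSD3 at 3.53-fold (2.32-5.61), SDF2L1 at 3.46-fold (2.44-5.05), RAC3 at 2.71-fold (2.00-3.73), UNC119 at 2.67-fold (1.97-3.69) and NDUFAF8, an assembly factor of respiratory complex I, at 2.65-fold (1.99-3.58). Lower were CCN1 at 4.23-fold (3.84-4.67), GADD45B at 3.33-fold (2.40-4.63), the matrix metalloproteinase gene MMP7 at 3.24-fold (2.80-3.75) and SCD, a fatty acid desaturase gene, at 2.66-fold (2.30-3.09). The NF-kB list had a median of -1.58 over 5 measured members. Genes at least 2-fold apart were 30 higher and 42 lower among 3909, and 44 and 43 without the 5% of cells with the most counts.

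**Figure D2:**
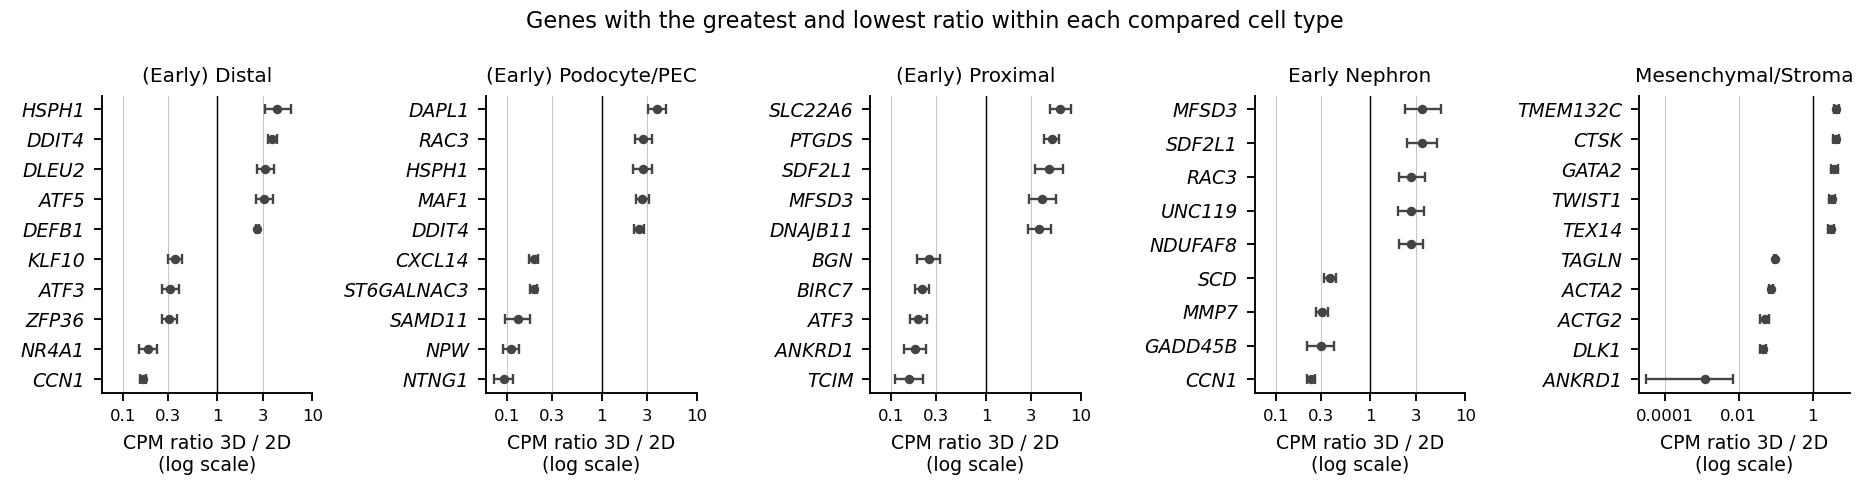
Ratio of CPM in the 3D to the 2D library (log axis; the stroma panel has a wider range) for up to 5 highest and 5 lowest genes of each compared type, with exact 95% Poisson intervals as bars. SLC22A6 stands at 6.06 in proximal cells, and 4 stroma genes stand near or below 0.1 besides ANKRD1.

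Some genes differed in the same direction in each of the 5 types. CCN1 was at least 2-fold lower in 3D in all 5, with ratios from 0.163 to 0.440, and so was the unnamed gene ENSG00000290848, given here only because the count was 2. No gene was at least 2-fold higher in all 5. By the weakest ratio over the types, the 10 genes most uniformly higher in 3D were the proteasome gene PSMD3 (1.98 to 2.19), MAF1 (1.99 to 2.68), DDIT4 (1.95 to 3.81), the chaperone gene HSPA8 (1.72 to 2.70), UNC119, NDUFAF8, DNAJB11, VPS51, SNRNP25 and WBP1. The 10 most uniformly lower were CCN1, CLEC5A, ASTN2, the immediate early genes FOS (0.471 to 0.592) and EGR1 (0.482 to 0.608), KLF10, SLC26A3, PPP1R15A, HES1 and RPSA2, of which the last is a near copy of RPSA and uncertain. Of 2444 genes with at least 50 CPM in every type, 711 were higher and 320 lower in all 5 types. The types share the same libraries, so a difference of the whole library or of its scaling would also give genes the same sign in all of them. The log2 ratios of different types correlated across genes with r from 0.387 (proximal with stroma) to 0.741 (proximal with Early Nephron), though genes are not independent replicates.

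Several gene lists went the same way in all 5 types or in the 4 nephron types. Immediate early genes, induced within minutes of a stimulus, had a median log2 ratio of -0.88 in distal cells, -0.82 in podocytes, -0.59 in proximal cells, -0.78 in Early Nephron cells and -0.73 in stroma, each below the central 95% of random lists. FOS was at 1940.3 CPM in 2D and 958 CPM in 3D in podocytes and EGR2 at 29.9 CPM in 2D and 2.95 CPM in 3D in distal cells. Heat shock genes were higher in each type, with medians of 0.53, 0.41, 0.51, 0.63 and 0.40 in the same order. HSP90AA1 was at 411 CPM in 2D and 651 CPM in 3D in distal cells and HSPA8 at 90.5 CPM in 2D and 244 CPM in 3D in stroma, where the abundant HSPB1 was lower at 538 CPM in 2D and 439 CPM in 3D. All 23 nuclear genes of oxidative phosphorylation were higher in each of the 4 nephron types, with medians from 0.26 (Early Nephron) to 0.45 (proximal), while the median of 0.09 in stroma lay within random lists. After correction for the genomic span of genes, an alternative chosen after the data were seen, the medians were 0.23 in podocytes, 0.32 in proximal cells and 0.18 in Early Nephron cells, the last within random lists. In proximal cells COX7C was at 1659.9 CPM in 2D and 2153 CPM in 3D and NDUFS6 at 167 CPM in 2D and 297 CPM in 3D. Targets of hypoxia-inducible factors had medians of -0.25, -0.35, -0.44 and -0.48 in distal, podocyte, proximal and Early Nephron cells, with SLC2A1, the glucose transporter GLUT1, at 1066 CPM in 2D and 631 CPM in 3D in podocytes. In stroma the list was not apart, at 0.08 (random lists -0.11 to 0.22). DDIT4 belongs to this list too and went the other way. Targets of BMP signalling were lower in each of the 5 types, from -0.21 in stroma to -0.71 in Early Nephron cells, and ID1 was at 2161 CPM in 2D and 1007 CPM in 3D in distal cells. The BMP list came within random lists in podocytes with all detected members (-0.33) and in stroma with 10 CPM added (-0.17). TGF-beta targets were lower as well, from -0.25 in stroma to -0.76 in Early Nephron cells. Cholesterol synthesis was lower in the nephron types by less than in stroma, from -0.24 in podocytes to -0.61 in Early Nephron cells. Each of these directions was the same when libraries were scaled by the median of ratios. That scaling moved all genes of a type alike, by -0.02 (podocytes) to -0.07 (stroma) in log2, so it could hardly turn them. With 10 CPM added in place of 1 CPM, medians over weakly expressed members were smaller, at -0.94 in podocytes and -0.77 in Early Nephron cells for the NF-kB list, -0.80 for stromal markers in Early Nephron cells and -0.35 for loop of Henle markers in distal cells.

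**Figure D3:**
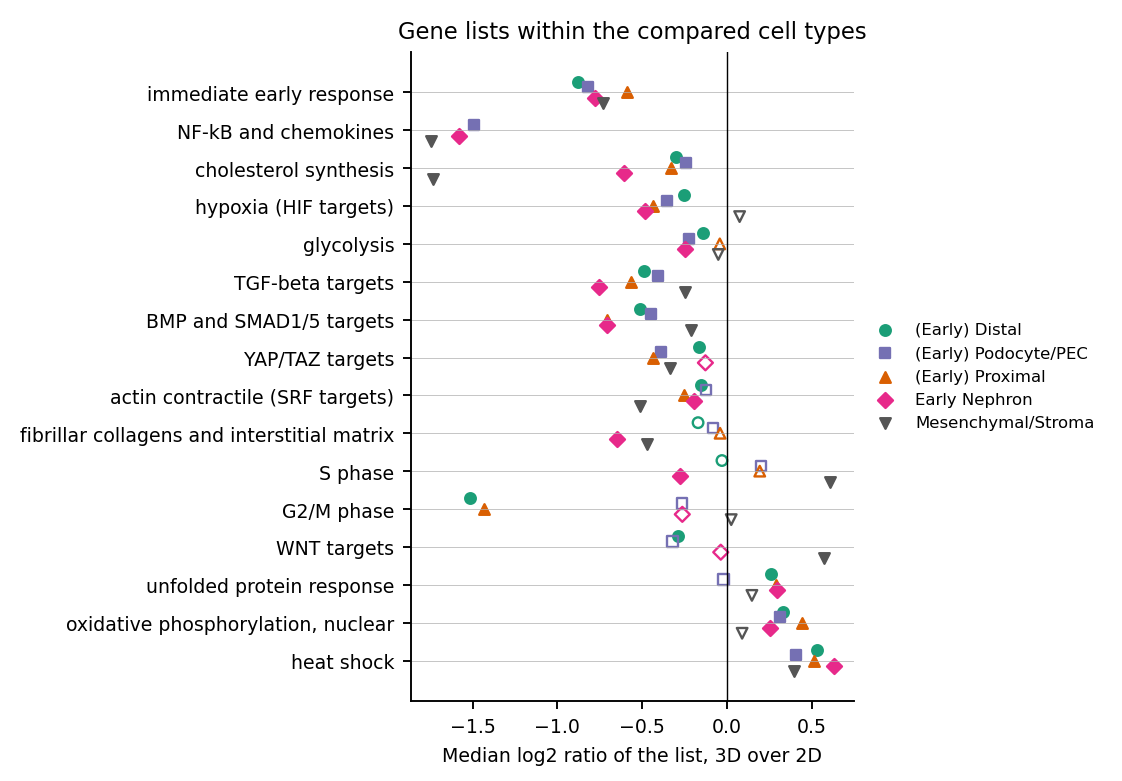
Median log2 ratio (3D over 2D) of 16 gene lists in the 5 compared cell types. Filled points lie outside and open points inside the central 95% of random lists matched on expression. In stroma, cholesterol synthesis lies at -1.73 and the NF-kB list at -1.75.

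Transcripts of G2/M genes gave no uniform picture. After every cell was thinned to 2000 counts, which left out no cell, at least 2 counts over the G2/M list were found in 18.2% (15.9-20.6) of stromal cells in 2D and 19.7% (17.7-21.9) in 3D. In distal cells the shares were 4.75% (15 of 316) and 2.07% (12 of 579), a ratio of 0.437 (0.187-0.999), against 22.8% and 24.2% without thinning. Podocytes were at 4.02% and 4.46%, proximal cells at 3.92% and 1.68%, and Early Nephron cells at 8.11% and 3.64%, with intervals of the ratio that included 1. Thinned to 1000 counts, the ratio was 0.136 in distal cells and turned to 1.26 in Early Nephron cells, from 0.448. The summed counts of distal cells had the G2/M list lower in 3D, with a median log2 ratio of -1.52 (random lists -0.53 to 0.46) and TOP2A at 32.0 CPM in 2D and 6.23 CPM in 3D. Proximal cells had all 8 measured members lower, with a median of -1.43 (random lists -0.60 to 0.35). With 10 CPM added these medians were -0.65 and -0.75. In the 2D library, the abundant Early Epithelial cells had such transcripts in 29.4% of cells, and free RNA from them was not removed from the other types.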

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

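Chosen only after the results were seen were the tests of the mesenchyme removal, of trypsin time, of genomic span on the oxidative phosphorylation list, and of doublets by connecting tubule genes and by collagens, the use of 3D cells named Early Epithelial as a control, and the 10 Early Epithelial genes picked by hand from the 20 leading genes of that type (SPRR2F, NPY, LHX9, SFRP2, GATA4, STAR, AMHR2, MYRF, WNT2B and NRK).

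Barcodes without a cell type label entered no comparison. Of the unlabelled 2D barcodes with at least 1000 counts, thinned to 1000, 18.3% (686 of 3743) carried at least 3 of the 10 Early Epithelial genes, against 0 of 1851 in 3D. Among labelled 2D cells at 2000 counts, 63.1% of Early Epithelial cells did so, against 12.6% of stroma and 1.58% of distal cells.

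The excess of Early Epithelial cells in 2D was weighed against 4 explanations. A removal of the mesenchymal layer that took other types alike would leave the number of Early Epithelial cells per distal or proximal cell unchanged. There were 564-fold (290-1249) more Early Epithelial cells per distal cell in 2D than in 3D and 479-fold (240-1075) more per proximal cell, which follows from the shares above. Whether the removal took the other types alike was not measured, so these values argue only against a removal that did. At least 3 of the 10 genes were carried by 1 of 3807 labelled 3D cells (0.0263%) and 1900 of 5156 in 2D (36.9%), a ratio of 0.000713, and among unlabelled barcodes the ratio was 0 (upper limit 0.0109). These genes came from the 2D cells, however, and 0 of the 9 3D cells named Early Epithelial carried 3 of them, so that 3D cells of this kind under another name, or below the gene minimum of the annotation, stay open. Also open is any other difference between these cultures or libraries than the format, with 1 library per format. The format itself remains an untested biological explanation, and a population found almost only in 1 library may belong to that library.

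The direction that immediate early and heat shock genes share across types was weighed against properties of the transcripts and against trypsin time. After correction for GC content, the averaged median log2 ratio of the immediate early genes was -0.83 against -0.76 before, 109% of its size, and that of the heat shock genes 0.46 against 0.50, 92.3% of its size. After correction for the genomic span of genes, which would track reads from introns or nuclei, the sizes were 108% and 93.8%. Neither trend could therefore be the whole cause for these 2 lists, but in the nephron types the oxidative phosphorylation list kept 70.4% to 90.7% of its median after the correction for span, which leaves span open there. The longer trypsin treatment of the 2D wells might raise immediate early genes, but with 1 library per format the time and the format cannot be told apart.

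The 3D library also held 84 unlabelled barcodes with at least 10000 genes, against 7 in 2D. They had a median of 84154 counts, against 9260 in labelled 3D cells. The connecting tubule genes GATA3 and CALB1 summed to 376 CPM in them, 0.155 (0.145-0.166) of the 2430 CPM in labelled Connecting Tubule cells, but labelled distal cells had 315 CPM, so that this level does not tell doublets from distal cells. The stromal genes COL1A1 and COL3A1 stood in these barcodes at 0.0468 (0.0424-0.0514) of their level over all labelled 3D cells. Pairs drawn evenly from the labelled 3D cells would hold more of them. A limit of 10000 genes favours cells with many genes, however. Of the compared types in 3D, stroma had the lowest median, 3459 genes, with podocytes at 3642 and proximal cells at 5308. The collagens therefore do not decide on random doublets that pass the limit. Doublets among nephron cells, also with a connecting tubule cell, stay open too. NPHS1, COL1A1, COL3A1 and AGT together stood at 0.504 (0.493-0.516) of their level over all labelled 3D cells, carried by NPHS1 at 438 CPM and AGT at 399 CPM. No biological explanation was tested.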

How the results depend on the processing

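The minimum of 5000 counts, shares without Early Epithelial cells and the corrections for GC content and genomic span were chosen after the data were seen; the others were planned. No paired analysis was possible because there was 1 library per format, both numbered replicate 1, and for the same reason no replicate could be left out. The planned filters of at least 1000 counts and at most 10% mitochondrial counts removed no labelled cell and so say nothing about stability. Of the values under the other alternatives, 470 of 480 for gene lists, 221 of 250 for named genes, 28 of 46 for shares, 39 of 56 for counts of genes and 12 of 15 for G2/M shares stayed the same, and no named gene changed direction. The list values came only from the 80 medians that lay far out among random lists. Those for named genes came only from the 50 highest and lowest ratios within types. Values picked as extreme could hardly change direction, so these tallies do not show how stable other lists and genes are. A value counted as the same if it lay within the 95% interval of the main value (for lists, over resampled members), and a count of genes if within 1.5 times the main count, so that precise values move more readily.

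Over nephron cells only, the ratio of shares was 1.14 for distal, 1.15 for Early Nephron and 6.08 for Nephron Progenitor cells, and it reversed to 0.739 for podocytes and 0.967 for proximal cells. Without Early Epithelial cells it was 1.15 for distal, 1.17 for Early Nephron, 0.318 for endothelial, 6.15 for Nephron Progenitor and 7.12 for neural progenitor cells, and it reversed to 0.746 for podocytes, 0.977 for proximal cells and 0.848 for stroma. By construction, these follow from the smaller denominators. With at least 5000 counts the ratio was 2.05 for distal cells, 1.83 for podocytes and 1.08 for tubule cells per podocyte, while without the 5% of cells with the most counts it was 1.79 for tubule cells per podocyte and 1.04 for endothelial cells. Podocytes had the fewest counts per cell of the nephron types in both libraries, and beyond that the cause was not tested.

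Genes at least 2-fold apart in distal, podocyte, proximal, Early Nephron and stromal cells numbered 156, 250, 262, 222 and 350 with a minimum of 20 CPM and 12, 29, 23, 14 and 33 with 200 CPM, as more or fewer genes are admitted. Without mitochondrial and ribosomal protein genes in the total, distal cells had 82 (33 higher, 49 lower in 3D), and scaled by the median of ratios 20 higher and 41 lower, against 27 and 26. Genes at least 2-fold lower in every type were 4 with 20 CPM and 4 without mitochondrial and ribosomal protein genes, and 1 each with 200 CPM, without the 5% of cells with the most counts, and with at least 5000 counts, while 1 gene was higher in every type without the 5% of cells with the most counts. With all detected members, the list of general nephron epithelium markers in stroma reversed from -0.59 to 0.17, since members under 10 CPM then count. The ratio of G2/M shares was 0.136 for distal cells at 1000 counts, and for Early Nephron cells 1.26 at 1000 counts and also 1.26 with at least 3 counts, on few cells. Except where the construction is named, the cause was not tested. Of the compared types, proximal and Early Nephron had the fewest cells in 2D, 153 and 148, and the fewest summed counts there, 2551923 and 1439487.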

Other observations

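Both tests of the hypothesis below were set before their results were seen, but the genes named in the first paragraphs and the use of the spread over list members were chosen afterwards.

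Stroma of the libraries differed in genes of the basement membrane, with a median log2 ratio of -0.29 (random lists -0.10 to 0.22): COL4A1, a collagen IV chain, was at 342 CPM in 2D and 115 CPM in 3D and NPNT at 36.5 CPM in 2D and 3.34 CPM in 3D. With all detected members the median was -0.45.

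Early Epithelial cells of the 2D library differed from the other labelled 2D cells in genes outside the kidney lists. LHX9 and GATA4, transcription factor genes of the early gonad and body cavity lining, were 14.5-fold (12.8-16.4) and 13.3-fold (11.7-15.2) higher there. AMHR2, the receptor of anti-Müllerian hormone, was 7.94-fold higher, and STAR, which moves cholesterol into mitochondria for steroid synthesis, 8.73-fold. SPRR2F was 14.3-fold and the peptide gene NPY 10.7-fold higher. General nephron epithelium markers were low in them, with a median log2 ratio of -4.20, HIF targets stood at -2.08, and G2/M genes at 1.33. The 137 Nephron Progenitors of the 3D library were led by GSTA1, and their 20 leading genes held the progenitor gene EYA1 (22.6-fold over other 3D cells). Also among the 20 were STMN2 (25.8-fold), a neuronal gene, PAX3 (18.9-fold), a gene of muscle and neural crest precursors, and COL2A1 (8.22-fold), the cartilage collagen. EYA1 also acts in muscle precursors, and SIX2, a specific marker of nephron progenitors, was not among the 20 leading genes. Neural progenitors of the 3D library were led by RFX4, RMST and FABP7. Their 20 leading genes also held WNT1 (526-fold), GDF7 (302-fold) and MSX1 (33.4-fold), known from the roof plate of the neural tube, and SOX2 (45.3-fold).

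A hypothesis drawn from these genes is that Early Epithelial cells may carry a program of the coelomic and gonadal epithelium. It was tested on genes of that epithelium that had not been seen among the leading genes, 15 of 23 of which were measured, and required a median log2 ratio above 1. The median over the other labelled 2D cells was 0.48, which fell short of that and lay just under the limit of 0.5 set beforehand against the hypothesis. It was above matched random lists (-0.44 to 0.22), but resampling of its members gave a range from -0.66 to 1.44, so the test is left open. The bearing of this range was considered only after the value was known, and without it the hypothesis would have been rejected. NR5A1 (18.7-fold), GATA6 (4.64-fold), NR0B1 (3.53-fold) and RSPO1 (3.07-fold) were higher, and TCF21 (0.199) and PAX8 (0.0223) far lower. Some genes of the list are also markers of the nephron and stromal cells that made up the reference. TCF21 was at 234 CPM and PAX8 at 91.2 CPM in those cells, so the choice of reference bears on such ratios and on the median. Genes of mesothelium, the lining of body cavities, had a median of 0.95 (resampled range 0.16 to 1.69, random lists -0.41 to 0.32) over 10 of 16 measured members, also short of 1. BNC1 was 11.1-fold, LRRN4 6.43-fold and PDPN 3.33-fold higher, while KRT19 stood at 0.792. Among the fixed lists, picked here after the values were seen, genes of epithelial polarity and junctions were low in these cells. Their median was -2.05 (random lists -0.46 to 0.21), with 2 of 15 measured members higher. Stromal markers, at -0.16, lay within random lists (-0.33 to 0.32). The keratin genes KRT8 and KRT18 were 1.99-fold and 2.29-fold higher. These data do not decide which epithelium, if any, the cells resemble.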
